A study of Homo sapiens with 6 samples.

How the data were processed

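RNA was measured in NTERA2/D1, an established human testicular teratocarcinoma line that keeps the features of pluripotent embryonal carcinoma cells. Per the labels, cells were transfected 24 h after plating, either with a nonspecific scrambled siRNA or with siRNA against VAMP7, and total RNA was taken after 72 h of transfection. Each group held 3 arrays, and each array was 1 sample. The sample titles number biological replicates 1 to 3 in each group, while the descriptions of all 3 knockdown samples carry the number 1. The labels do not say whether the replicates were separate cultures or days, so the p-values measure the spread between these samples, which may be technical. No pair of arrays held identical values.

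The deposited values were intensities on a linear scale, 1 per probe set of a human whole-transcriptome 3' expression array, with 54675 probe sets per array. Each array had a trimmed mean of 500.07 after leaving out 2% of its values at each end, so the deposited intensities had been scaled to the same target on every array. The submitters' processing notes name RMA without a version. RMA gives log2 values with the same distribution on every array, which does not describe these linear values, whose medians ran from 58.85 to 67.54. The background correction and the software behind the deposited intensities are not given in the sources used here. The tests had been planned for log2 values, so the intensities were put on the log2 scale here after an offset of 50 was added. The offset was chosen once the scale was known, from the spread within groups and before any comparison of groups. Fold changes are therefore on the log2(intensity + 50) scale, which understates the change of dim genes. No detection calls were used, and the number of arrays limits the precision.

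Probe sets were named from the platform annotation, and symbols were updated through gene identifiers to a reference gene table of GRCh38.p14, used for names only. Of the probe sets, 41091 named 1 gene, 1801 named several genes, 11721 had no listed gene and 62 were array controls. The identifiers of 41037 of the 41091 matched the reference table (99.87%), and the others kept their older symbol. Genes were taken only from probe sets that named 1 gene. The probe set with the highest mean over the 6 arrays stood for its gene, which gave 19775 genes, and no filter was set on dim genes.

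Knockdown was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without trend or robust options, and with Benjamini-Hochberg adjustment over the 19775 genes. A gene was called at an adjusted p under 0.05. An exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1, so none was used for calls. The 34 gene lists and the rules below were fixed before the data were examined. The lists held 1456 genes, 1316 of them measured, with VAMP7 left out of every list. The least complete lists were those of HOX genes (33 of 44 measured), ribosomal proteins (51 of 77) and histones (23 of 37). Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were run beside it. A list score was the mean log2 value of its members on an array after centring the array on its mean gene.

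The genes named were VAMP7, 10 in each direction, 2 members of each list that had no called member, and a fixed set of genes (ESR1, ESR2, PGR, POU5F1, NANOG, SOX2 and LIN28A). One further gene of the fixed set is not reported here. The 10 were taken from genes whose 3 knockdown arrays all lay beyond all 3 control arrays and whose brighter group was at or above the median gene. Uncharacterised loci, antisense genes and pseudogenes were passed over. Fewer than 5 genes passed the threshold in either direction, so the 10 were ranked by unadjusted p, as the rule provides, and VAMP7 itself was 1 of the 10 lower genes.

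The code was tested on simulated arrays made from the real gene means, with 200 of the 19775 genes changed, in 20 simulations. The spreads were those after moderation by eBayes, which are more alike than the genes' own spreads. It called 27.9% of the genes changed 1.5-fold, 86% of those changed 2-fold, 98.2% of those changed 3-fold and 99.6% of those changed 4-fold. A list of 50 simulated genes shifted by 0.15 on the log2 scale was called in 100% of the simulations, where genes varied independently. The alternatives tried covered dim-gene filters, the use of all probe sets or their mean, median centring, quantile normalization, eBayes options, array weights, the replicate number as a block, other offsets and the omission of each array. Each gene kept its probe set when an array was left out, the offset changed or the values were quantile normalized, and these were also run with the probe set of highest mean chosen anew.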

Results

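Gene expression was measured with 3' expression arrays in NTERA2/D1 cells, a human testicular teratocarcinoma line, on 3 arrays after transfection with scrambled siRNA (control) and 3 after transfection with siRNA against VAMP7 (knockdown). The comparison asks which transcripts and pathways differ when the expression of VAMP7 is lowered. Median intensity ran from 58.85 to 67.54 across the arrays. Knockdown replicate 1 stood apart from the other arrays, with a loading of 0.90 on the first principal component, which held 29.5% of the variance, and a mean correlation of 0.9879 with the other arrays, against 0.99 to 0.991 for the rest. Settings in which the probe set of highest mean was chosen anew, and lists tested with the correlation estimated under an alternative setting, were added after the results had been seen.

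VAMP7, a vesicle SNARE of late endosomes and lysosomes, fell in the knockdown. Its probe set read 2615 ± 127 intensity units in control and 153.6 ± 19.8 in knockdown (SD, n = 3 each), so 5.87% of the control signal remained, a 17-fold difference. The 3 control arrays read 2487, 2617 and 2741, and the 3 knockdown arrays read 136.8, 175.4 and 148.6. The log2 fold change was -3.71 (SE 0.11, 95% interval -3.97 to -3.46, adjusted p = 8.65e-05 in limma). No other probe set named VAMP7 alone.

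**Figure D1:**
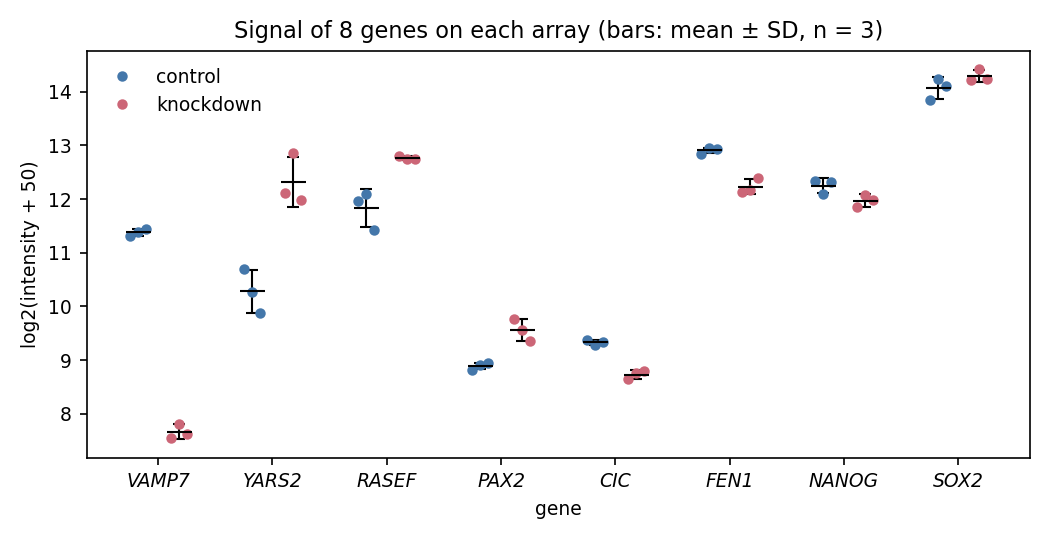
Log2(intensity + 50) of named genes on each array, with control arrays in blue and knockdown arrays in red; black bars give the mean and SD of 3 arrays. VAMP7 was lower on every knockdown array, while YARS2, RASEF, PAX2, CIC and FEN1 did not pass the adjusted threshold.

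No other gene passed. Limma called 0 genes higher and 1 gene lower among 19775, and the second smallest adjusted p was 0.0968, for C19orf73, a dim gene named after its value was seen, which read 11.5 ± 0.97 in control and 71.2 ± 4.43 in knockdown (SD, n = 3). Genes are called dim where their mean lay below that of the median gene, 8.09 on the log2 scale. At an unadjusted p under 0.05 there were 1317 genes (6.66%), 718 higher and 599 lower, against 989 expected by chance. Among genes at or above the median signal the share was 5.42% in this fit. When these 9888 genes were fitted alone it was 8.89% (879 genes), and VAMP7 was again the gene called. The count of genes at this threshold therefore depended on whether dim genes entered the fit. The groups did not overlap for 2563 genes (12.96%), where chance gives 10%. The median standard error was 0.135 on the log2 scale, 0.114 for genes at or above the median signal and 0.171 for those below it. In the simulated comparison, with 200 of 19775 genes changed, 86% of 2-fold and 27.9% of 1.5-fold changes were called. These simulations called 164.2 genes on average, which makes the adjusted threshold easier to pass than here, where 1 gene was called. The shares are therefore not the power of the real comparison.

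**Figure D2:**
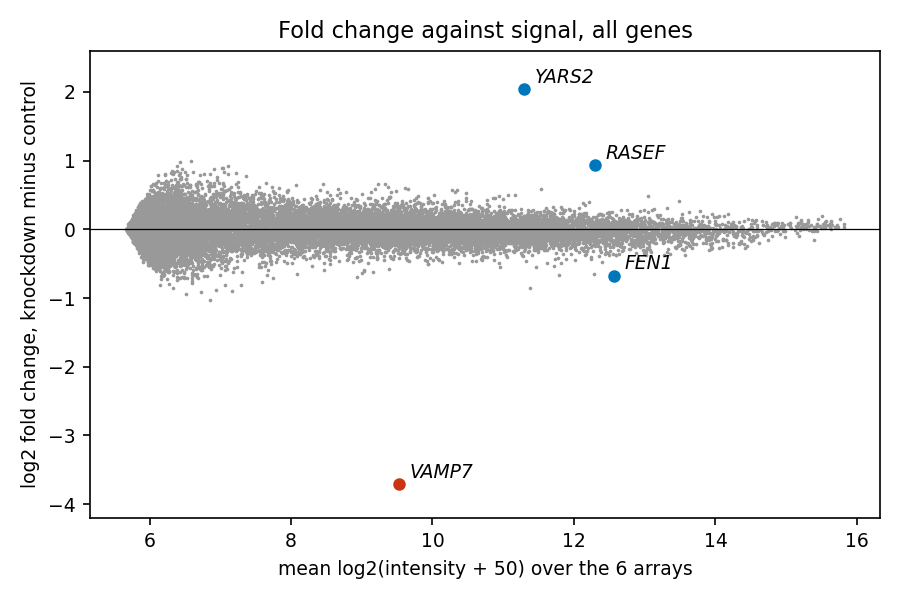
Log2 fold change (knockdown minus control) of each of the 19775 genes against its mean log2(intensity + 50) over the 6 arrays. VAMP7, in red, is the gene that passed the adjusted threshold, at -3.71; YARS2, RASEF and FEN1, in blue, are labelled and did not pass.

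The following genes, ranked by unadjusted p because fewer than 5 passed in either direction, did not pass the adjusted threshold. YARS2, the mitochondrial tyrosyl-tRNA synthetase, read 1227 ± 359 in control and 5241 ± 1820 in knockdown (SD, n = 3). Its log2 fold change of 2.04 (SE 0.28, adjusted p = 0.461) was the largest among genes of at least median signal other than VAMP7. RASEF, a Rab-family GTPase with EF-hand motifs, read 3661 ± 840 and 6927 ± 168, a log2 fold change of 0.94 (adjusted p = 0.47). PAX2, a transcription factor of kidney and genital tract development, had a log2 fold change of 0.67 and PAQR6, a membrane progesterone receptor, one of 0.66. The remaining 6 on the higher side were ACAP3, COL27A1, FTX, IMPDH1, CHTF18 and FZD1, a WNT receptor, with log2 fold changes from 0.46 for CHTF18 to 0.57 for ACAP3. Among the lower genes after VAMP7, FEN1, the flap endonuclease that processes Okazaki fragments, read 7633 ± 272 in control and 4780 ± 499 in knockdown (SD, n = 3), a log2 fold change of -0.67 (adjusted p = 0.461). CIC, a transcriptional repressor, had a log2 fold change of -0.60, TNNC1, the slow and cardiac troponin C, -0.64, and PDCD10, a cavernous malformation protein, -0.65. JAM2, VAMP8, APOC1, GSR and FAM91A1 lay between -0.59 and -0.44. Other probe sets disagreed for several of these genes. A second FEN1 probe set gave 0.09, a second GSR probe set 0.02 and a second JAM2 probe set 0.17. Their mean intensities were 2552, 577.8 and 405, against 6207, 1536 and 485.7 for the probe sets used. A RASEF probe set of mean intensity 3509 gave 0.61, against 5294 for the one used. Its others gave 0.28, -0.002 and -0.15, at 10.58, 59.98 and 4.951. A second FAM91A1 probe set gave 0.17, at 51.13. Second probe sets of PAX2 and ACAP3 gave 0.10 and 0.07, at 108.1 and 124.3. Those of FZD1 gave -0.06 and -0.11, at 98.81 and 82.38. The scale used understates changes at such dim signals, most at the dimmest. The second probe sets of FZD1 (SE 0.11 and 0.12), PAX2 (SE 0.22) and ACAP3 (SE 0.17) read above the offset of 50. They did not show the rise of the probe sets used, and the one used for ACAP3 read 203.8 itself. Whether these genes changed stays open. COL27A1 and FTX were above 0 and APOC1 below 0 on all of their probe sets. With an added intensity trend among genes at or above the median signal, a setting chosen after its counts had been seen, YARS2 (adjusted p = 0.0117) and FEN1 (adjusted p = 0.0388) passed.

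Among the sex steroid receptors, the oestrogen receptors ESR1 and ESR2 were dim. ESR1 read 46.6 ± 17.1 in control and 58.1 ± 7.59 in knockdown, and ESR2 read 23.2 ± 13.4 and 25.2 ± 14.1 (SD, n = 3). The progesterone receptor PGR had a log2 fold change of 0.17 (adjusted p = 0.848), or 0.07 without knockdown replicate 1. That of ESR1 was 0.02 without control replicate 2 and turned below 0 with its probe set of smallest p, and that of ESR2 turned below 0 when any of 3 arrays was left out, with the mean of its probe sets and with that of smallest p. Of the 51 measured oestrogen receptor targets, 24 lay above 0 and 27 below (camera adjusted p = 0.824), with IGF1R at 0.28 and TPD52L1 at -0.26. The steroid receptors and coregulators list had 20 of 35 members above 0 (adjusted p = 0.918), with ESRRG at -0.37 and PELP1 at 0.24. Its median was 0.01 and its mean -0.02. The genital and gonadal development list had 23 of 43 members above 0 (adjusted p = 0.899), with a median of 0.02 and a mean of -0.004. Its members of smallest p were EMX2, a homeobox gene of the urogenital system, at 0.44 and SHH at -0.52.

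No list of the membrane trafficking machinery passed. The SNARE and VAMP7 partner list had 25 of its 55 measured members above 0 and 30 below (camera adjusted p = 0.824). VAMP8, another endosomal SNARE, read 241.7 ± 24.1 in control and 157.4 ± 20.7 in knockdown (SD, n = 3; log2 fold change -0.49, adjusted p = 0.565), and NAPB was at 0.40. In the endosomal trafficking list 46 of 65 members lay below 0 (median -0.05, adjusted p = 0.424), among them RAB35 at -0.48 and the clathrin light chain CLTB at -0.34. Of the 34 lists it had the smallest unadjusted p in camera with an estimated correlation (0.0698) and in fry (0.0252). It passed neither test after adjustment (0.925 and 0.57). The lysosome list (53 measured, adjusted p = 0.824) had TFEB, a lysosomal transcription factor, at -0.62, and IGF2R at 0.23. The autophagy list (43 measured, adjusted p = 0.824) had the kinase ULK1 at 0.40 and WIPI1 at -0.50, or -0.23 without knockdown replicate 1. Of 53 genes of neurite outgrowth and synaptic vesicles, 34 lay above 0 (adjusted p = 0.57), with SYP at 0.30 and EPHA4 at 0.20.

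One list was called, oxidative phosphorylation, which fell at the preset correlation (camera adjusted p = 3.58e-07) but was not called with an estimated correlation (0.925) or with fry (0.57). The estimated correlation of its members was 0.228, against the preset 0.01. With the correlation estimated, the list was not called in any of the alternative settings where that was run (adjusted p = 0.125 to 0.977). Of its 52 measured members, 47 had a log2 fold change below 0, with a median of -0.11 and a mean of -0.14. The size depended on the choice of probe set: the mean was -0.094 with the mean of a gene's probe sets (43 of 52 below 0) and -0.067 with all probe sets (79 of 109 below 0). NDUFA2, a subunit of respiratory complex I, was at -0.49 (adjusted p = 0.612) and UQCRQ, of complex III, at -0.30. The mean of a gene's probe sets turned NDUFA2 to 0.07. No single member passed, and 5 were lower and 0 higher at an unadjusted p under 0.05. The list score was 4.48 ± 0.083 in control and 4.34 ± 0.046 in knockdown (SD, n = 3). Control replicate 1, at 4.38, lay 0.012 above the highest knockdown array. The groups did not overlap for 5 other lists, none of which passed: trophoblast markers (gap 0.028), endosomal trafficking (0.027), replication-dependent histones (0.008), neural markers (0.005) and S phase (0.001).

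**Figure D3:**
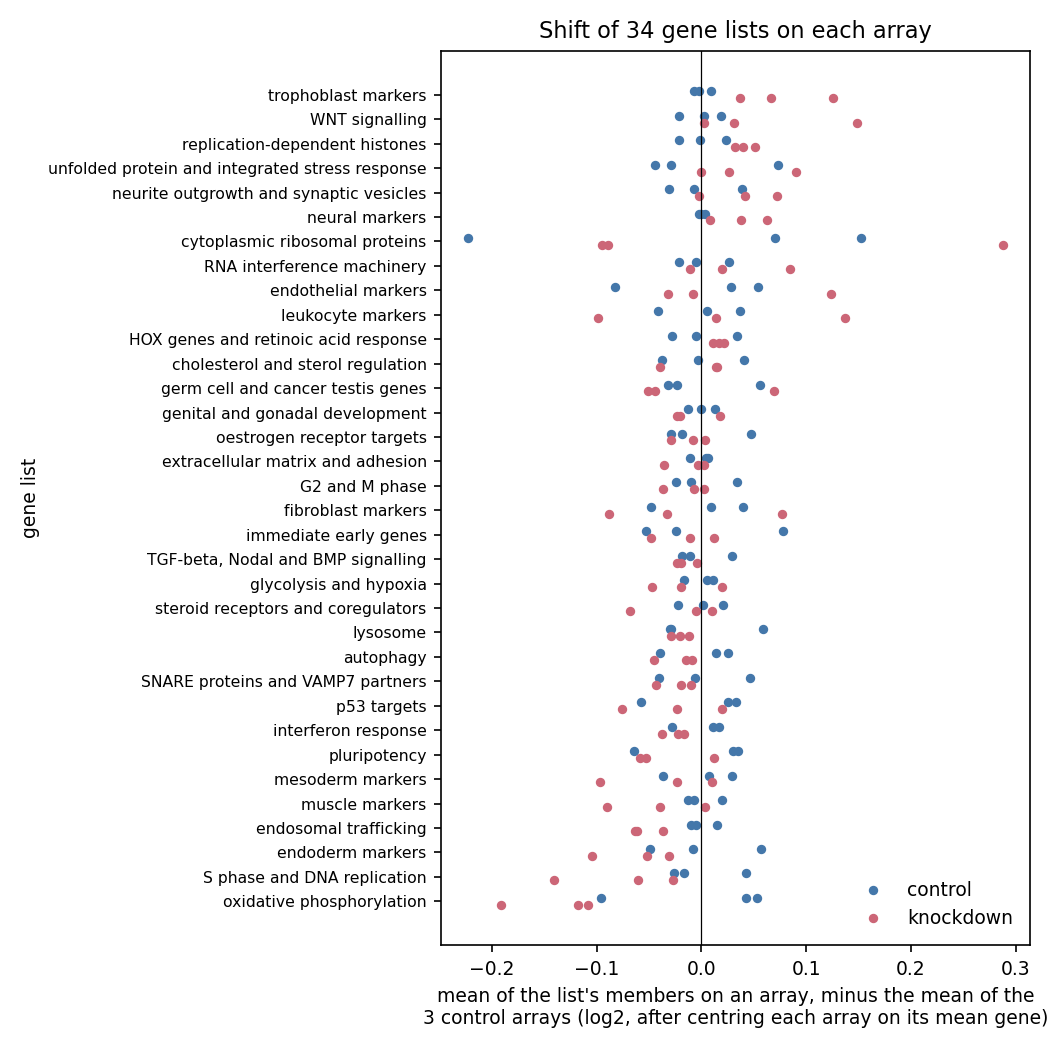
Shift of each of the 34 gene lists on each array, as the mean log2 value of its members after centring the array on its mean gene, minus the mean of the 3 control arrays; control arrays are blue and knockdown arrays red. The oxidative phosphorylation list, at the bottom, had its 3 knockdown arrays below its 3 control arrays by a gap of 0.012, narrower than those of trophoblast markers (0.028) and endosomal trafficking (0.027), and the ribosomal protein list spread most within both groups.

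None of the other 33 lists passed, and 3 of the 34 had an unadjusted camera p under 0.05. Of the 56 measured genes of S phase and DNA replication, 36 lay below 0 (median -0.06, camera adjusted p = 0.119), FEN1 at -0.67 (0.09 on a second probe set) and EXO1 at -0.29 with the smallest p. That list was called lower without knockdown replicate 3 (0.0323) and with an intensity trend (0.0427), but in neither with the correlation estimated (0.896 and 0.935). The G2 and M phase list of 72 genes was near 0 (adjusted p = 0.904), with MKI67 at 0.22 and BUB3 at -0.31. Of 51 ribosomal protein genes 42 lay above 0 (median 0.03, adjusted p = 0.824), with RPLP2 at 0.46 and RPL27 at -0.16. The call on this list depended on single arrays: it was lower without knockdown replicate 1 (adjusted p = 0.0101) and higher without control replicate 2 (0.0291). With the correlation between its members estimated in these settings, 0.923 and 0.922, neither call was kept (adjusted p = 0.876 and 0.928). Replication-dependent histones (23 measured, adjusted p = 0.824) had H2BC21 at 0.38 and H2BC3 at -0.44. Glycolysis and hypoxia genes (39 measured, adjusted p = 0.824) had LDHA at -0.17 and SLC2A1 at 0.30. Cholesterol genes (32 measured, adjusted p = 0.904) had NSDHL at -0.22 and SC5D at -0.18, with a list mean of 0.001 and a median of -0.01. In the unfolded protein and integrated stress response list 35 of 43 members lay above 0 (median 0.05, adjusted p = 0.57), with CHAC1 at -0.27 and SDF2L1 at 0.25, and it was called higher without control replicate 2 (0.0493), but not with the correlation estimated (0.928).

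Markers of pluripotent cells did not pass the test. NANOG read 4839 ± 457 in control and 3968 ± 328 in knockdown (SD, n = 3; log2 fold change -0.28, adjusted p = 0.742). SOX2 was at 0.22 (adjusted p = 0.806), or 0.11 without control replicate 1. LIN28A was at 0.08 (adjusted p = 0.955) and turned below 0 with array weights and without control replicate 1 or knockdown replicate 1. POU5F1 was measured only by a probe set that names 4 genes, which was at -0.06 (SE 0.13). The pluripotency list had 21 of 42 members above 0 (camera adjusted p = 0.824), with the telomerase gene TERT at 0.53 and POLR3G at -0.45. Neural markers had 24 of 38 above 0 (adjusted p = 0.57), with NHLH1 at 0.37 and SYP at 0.30. Mesoderm markers (27 measured, adjusted p = 0.824) had PDGFRA, a receptor of platelet-derived growth factor, at -0.66 and TBX6 at 0.29, and endoderm markers (27 measured, adjusted p = 0.824) had CER1 at 0.54 and TF at -0.41. Trophoblast markers had 16 of 26 above 0 (adjusted p = 0.57), with INSL4 at 0.51 and ERVW-1 at 0.50, which turned to -0.13 without knockdown replicate 2 when the probe set was chosen anew. Germ cell and cancer testis genes (35 measured, adjusted p = 0.853) had CTAG2 at -0.37 and SYCP1 at 0.50, which turned to -0.01 without knockdown replicate 3 when the probe set was chosen anew.

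Markers of other cell types were at 0.904 (fibroblast), 0.824 (muscle), 0.904 (endothelial) and 0.853 (leukocyte) in adjusted p. Among them PDGFRA was at -0.66 and COL6A2 at 0.62 (fibroblast), and TNNC1 at -0.64 and TTN at 0.42 (muscle). ESAM was at 0.80 and VWF at 0.42 (endothelial), and CSF1R at 0.33 and CD79B at -0.41 (leukocyte). With the probe set chosen anew after an array was left out, TTN turned to between -0.16 and -0.12 without any 1 knockdown array, and CD79B to 0.18 without control replicate 1. TTN was also at -0.23 at an offset of 0 with the probe set chosen anew. The endothelial list had a mean of 0.03 and a median of -0.01, and the muscle list a mean of -0.04 and a median of 0.01. HOX and retinoic acid response genes (33 measured, adjusted p = 0.904) had HOXD4 at 0.82, and STRA6, a retinol transporter receptor, at 0.46, with a list mean of 0.02 and a median of -0.06. In the interferon response list 22 of 51 members lay above 0 (adjusted p = 0.824), with IFI44L at 0.62 and OASL at -0.67. WNT signalling genes had 33 of 46 above 0 (median 0.05, adjusted p = 0.446), FZD1 at 0.50 and DKK3 at -0.28. TGF-beta, Nodal and BMP signalling (47 measured, adjusted p = 0.824), extracellular matrix and adhesion (50 measured, adjusted p = 0.904), immediate early genes (41 measured, adjusted p = 0.824), p53 targets (32 measured, adjusted p = 0.824) and RNA interference machinery (20 measured, adjusted p = 0.824) did not pass. The TGF-beta, Nodal and BMP list had CER1 at 0.54 and THBS1 at -0.49, and the matrix list THBS1 and ITGA1, at -0.33. Immediate early genes had EGR1 at 0.28 and DUSP1 at -0.21 (0.06 with the mean of its probe sets). The p53 targets had POLH at -0.31 and RPS27L at -0.20, and RNA interference machinery DDX6 at 0.28 and AGO2 at -0.21.

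No list member passed over all genes tested, and 3 passed when adjusted over the list alone, 1 each in the muscle (TNNC1), interferon (IFI44L) and S phase (FEN1) lists. A second FEN1 probe set gave 0.09. IFI44L read 2.20 ± 0.68 in control and 30.5 ± 4.11 in knockdown (SD, n = 3), both below the median intensity of an array. Beside C19orf73, ESR1 and ESR2, the dim genes among those named were ACAP3, TNNC1, VAMP8, ESRRG, SHH, TFEB, WIPI1, SYP, RPLP2, H2BC21, H2BC3, TERT, NHLH1, PDGFRA, TBX6, CER1, TF, INSL4, ERVW-1, SYCP1, CTAG2, COL6A2, TTN, ESAM, CSF1R, CD79B, HOXD4, IFI44L, OASL, ITGA1 and POLH.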

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

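The alternative offsets, the filters combined with an intensity trend, the brightest 30% of the genes, the trend with robust option, quantile normalization of genes above the median signal, the settings with the probe set chosen anew and the correlation estimated within a setting were chosen after the data and their counts of genes had been seen. Choosing anew means that the probe set of highest mean was taken again after an array was left out, the offset changed or the values quantile normalized; elsewhere each gene kept its probe set, apart from the settings on all or the mean of its probe sets. The VAMP7 log2 fold change stayed below 0 and past the adjusted threshold in each of the 31 alternatives that gave it a value, from -4.10 at an offset of 0 to -3.42 at an offset of 100, with adjusted p from 1.83e-08 to 0.00764. No other VAMP7 probe set named it alone, so a second probe set could not be tried. The count of higher genes, 0, became 1 with the mean of a gene's probe sets and at offsets of 0 and 16 (C19orf73, adjusted p = 0.0375, 0.0184 and 0.0276; 0.0182 and 0.0274 at these offsets with the probe set chosen anew). It also became 1 among genes above the median signal and in the brightest 30%, both with an intensity trend (YARS2, adjusted p = 0.0117 and 0.0228). The count of lower genes, 1, became 2 among genes above the median signal with an intensity trend, where FEN1 passed beside VAMP7 (adjusted p = 0.0388), and 0 in the brightest 30%, which leaves out VAMP7 by its mean. In the brightest 30% with an intensity trend the 1 lower gene was FEN1 (adjusted p = 0.0356). Over its 33 alternatives, the adjusted p of YARS2 ran from 0.0117 to 0.773, and that of FEN1 from 0.0356 to 0.773. The log2 fold change ran from 1.77 to 2.24 for YARS2 and from -0.757 to -0.291 for FEN1. A second FEN1 probe set gave 0.092. Over all genes the deviations of same-numbered arrays correlated at -0.005, 0.013 and -0.014, which gave no sign of pairing but cannot exclude it. In the oxidative phosphorylation list replicate 1 scored lowest in both groups (4.38 in control and 4.29 in knockdown). With the replicate number as a block, the estimated correlation of that list was 0.019 (camera p = 0.0413, adjusted p = 0.925). The fit with the replicate number as a block gave 0 higher genes and 1 lower gene, a VAMP7 log2 fold change of -3.71 (adjusted p = 0.00661), 0 higher lists and 1 lower list.

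The count of lower lists, 1, became 2 with an intensity trend, alone or with the robust option, where S phase and DNA replication joined (adjusted p = 0.0427 for both), and 0 with an estimated correlation and with fry. With each array left out, it ran from 1 to 2 and the count of higher lists from 0 to 2. Without knockdown replicate 1 the ribosomal protein list was called lower (adjusted p = 0.0101, or 0.0105 with the probe set chosen anew), and without knockdown replicate 3 the S phase list was (0.0323 and 0.0447). Without control replicate 2 the ribosomal list (0.0291 and 0.029) and the unfolded protein response list (0.0493 and 0.0494) were called higher. With the correlation estimated in the same setting none of these lists was called, with adjusted p of 0.876 to 0.928 where the probe set was kept and 0.877 to 0.908 where it was chosen anew. The S phase list with an intensity trend, alone or with the robust option, was at 0.935 in both. The oxidative phosphorylation list was called lower in 34 of 36 alternatives, with adjusted p from 1.35e-10 to 0.925. With the correlation estimated it was not called in any of the 33 settings where that was run beside the preset correlation (adjusted p = 0.125 to 0.977); camera on ranks was run only at the preset correlation. The cause of these changes was not tested, except that fewer genes or arrays enter some settings. Of 2602 values of the 85 other named genes, 2575 kept their sign and side of the threshold and 23 had the opposite sign. ESR2 was -0.097 and -0.426 with the mean of its probe sets and with its probe set of smallest p, ESR1 -0.155 with the latter, and NDUFA2 0.068 and DUSP1 0.063 with the mean. LIN28A was -0.006 with array weights. With arrays left out, the log2 fold changes ran for ESR2 from -0.092 to 0.203 and LIN28A from -0.076 to 0.236. No other named gene turned when the probe set was kept. Most named genes had groups that did not overlap, and for these leaving out 1 array cannot turn the sign. The intensity trend and robust options do not alter a fold change. The share of values that kept their sign was therefore largely fixed by how the genes were picked. With the probe set chosen anew TTN was -0.227 at an offset of 0, and -0.16, -0.12 and -0.129 without knockdown replicates 1, 2 and 3. ERVW-1 was -0.133 without knockdown replicate 2, SYCP1 -0.011 without knockdown replicate 3 and CD79B 0.182 without control replicate 1. These turns followed the change of probe set, since the kept probe sets did not turn. ESR2 and LIN28A, each on the probe set they had, were -0.092 and -0.061 without control replicate 1 and -0.053 and -0.076 without knockdown replicate 1, and ESR2 was -0.039 without knockdown replicate 3. ESR2, CD79B, TTN, ERVW-1 and SYCP1 read under 100 intensity units in both groups, where signal over background limits a fold change.

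Of 1215 list values, 1104 kept their direction and side and 101 turned direction, over 21 lists, 2 of them past the threshold (ribosomal proteins without knockdown replicate 1, above). The adjusted p values of those that turned follow. Among genes above the median signal these were steroid receptors and coregulators 0.816, mesoderm markers 0.941, trophoblast markers 0.972, fibroblast markers 0.972 and germ cell and cancer testis genes 0.972. With the mean of a gene's probe sets these were lysosome 0.949, autophagy 0.939, fibroblast markers 0.81, cholesterol and sterol regulation 0.949 and TGF-beta, Nodal and BMP signalling 0.949. With all probe sets these were lysosome 0.809, autophagy 0.776, fibroblast markers 0.673, leukocyte markers 0.673, cholesterol and sterol regulation 0.941 and TGF-beta, Nodal and BMP signalling 0.99. With quantile normalization these were steroid receptors and coregulators 0.941, G2 and M phase 0.938, cholesterol and sterol regulation 0.998 and cytoplasmic ribosomal proteins 0.941. With array weights these were endothelial markers 0.82, cholesterol and sterol regulation 0.978 and cytoplasmic ribosomal proteins 0.713. At an offset of 0 this was leukocyte markers 0.895. Among genes above the median signal with an intensity trend these were steroid receptors and coregulators 0.826, mesoderm markers 0.931, fibroblast markers 0.948, extracellular matrix and adhesion 0.948 and germ cell and cancer testis genes 0.948. In the brightest 30% of the genes these were SNARE proteins and VAMP7 partners 0.969, autophagy 0.991, oestrogen receptor targets 0.882, steroid receptors and coregulators 0.515, muscle markers 0.851, G2 and M phase 0.969, glycolysis and hypoxia 0.882, extracellular matrix and adhesion 0.851 and germ cell and cancer testis genes 0.882. In the brightest 30% with an intensity trend these were SNARE proteins and VAMP7 partners 0.983, oestrogen receptor targets 0.863, steroid receptors and coregulators 0.562, muscle markers 0.839, G2 and M phase 0.983, glycolysis and hypoxia 0.874, extracellular matrix and adhesion 0.772 and germ cell and cancer testis genes 0.863. With quantile normalization of genes above the median signal these were steroid receptors and coregulators 0.601, mesoderm markers 0.961, trophoblast markers 0.966, fibroblast markers 0.961, G2 and M phase 0.942, cytoplasmic ribosomal proteins 0.942 and extracellular matrix and adhesion 0.961. Without control replicate 1 and with the probe set chosen anew these were oestrogen receptor targets 0.94, fibroblast markers 0.807, cytoplasmic ribosomal proteins 0.101, immediate early genes 0.807 and germ cell and cancer testis genes 0.94. Without control replicate 2 and with the probe set chosen anew this was endothelial markers 0.784. Without control replicate 3 and with the probe set chosen anew these were SNARE proteins and VAMP7 partners 0.963, lysosome 0.963, G2 and M phase 0.963 and cholesterol and sterol regulation 0.963. Without knockdown replicate 1 and with the probe set chosen anew these were endothelial markers 0.712, leukocyte markers 0.793, G2 and M phase 0.991, cholesterol and sterol regulation 0.893 and cytoplasmic ribosomal proteins 0.0105. Without knockdown replicate 2 and with the probe set chosen anew this was steroid receptors and coregulators 0.874. Without knockdown replicate 3 and with the probe set chosen anew these were fibroblast markers 0.86, glycolysis and hypoxia 0.993 and extracellular matrix and adhesion 0.993. At an offset of 0 with the probe set chosen anew these were leukocyte markers 0.892 and interferon response 0.987. With quantile normalization and the probe set chosen anew these were steroid receptors and coregulators 0.937, G2 and M phase 0.937, cholesterol and sterol regulation 0.995 and cytoplasmic ribosomal proteins 0.937. With fry this was G2 and M phase 1. With camera on ranks these were endothelial markers 0.893, HOX genes and retinoic acid response 0.872 and extracellular matrix and adhesion 0.996. Over the left-out arrays they ran as follows: oestrogen receptor targets 0.672 to 0.958, fibroblast markers 0.578 to 0.993, cytoplasmic ribosomal proteins 0.0101 to 0.622, immediate early genes 0.524 to 0.999, germ cell and cancer testis genes 0.66 to 0.999, endothelial markers 0.674 to 0.954 and SNARE proteins and VAMP7 partners 0.574 to 0.964. The others were lysosome 0.781 to 0.954, HOX genes and retinoic acid response 0.781 to 0.999, G2 and M phase 0.817 to 0.996, cholesterol and sterol regulation 0.817 to 0.954, leukocyte markers 0.521 to 0.952, steroid receptors and coregulators 0.832 to 0.964 and extracellular matrix and adhesion 0.829 to 0.999.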

Other observations

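The mixed test of the lists, the correlation estimated under alternative settings and the count of splits that called each list were chosen after the results had been seen, as were the genes CARTPT and DLG5-AS1.

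At least 2-fold differences at an unadjusted p under 0.05 were found for 4 genes, YARS2 and CARTPT higher, VAMP7 and DLG5-AS1 lower, of which CARTPT and DLG5-AS1 were dim. Among 13522 probe sets with no gene or several genes, limma called 0, and 918 had an unadjusted p under 0.05. Fry's mixed test asks whether members change in either direction. It gave adjusted p of 0.00159 for the interferon list, 0.00159 for histones and 0.0374 for HOX and retinoic acid response genes. In these lists IFI44L, OASL, H2BC3, H2BC21 and HOXD4 were dim. The test does not compare members with other genes, so it does not show that these lists changed more than the rest. At an unadjusted p under 0.05, 2 of 51 interferon members were higher and 2 lower, 3 and 3 of 23 histones, and 5 and 1 of 33 HOX and retinoic acid response genes. Over all genes the share was 6.66%.

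The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1 gene, VAMP7, the target of the siRNA, and the highest other split 0, so 1 split gave as many. The other splits mix both levels of VAMP7 in each group, so this count says nothing on other genes. At an unadjusted p under 0.05 the real split gave 1317 genes and the highest other 1089, and again 1 split gave as many. For the lists, the real split called 1 and the highest other 2, and all 10 splits gave at least as many.

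The oxidative phosphorylation list was lower after knockdown at the preset correlation (mean log2 fold change -0.14, or -0.094 with the mean of a gene's probe sets and -0.067 with all probe sets), but with an estimated correlation it was not called (adjusted p = 0.925), nor in any alternative setting where that was run (0.125 to 0.977). A single aberrant array does not account for the lower mean, which was -0.115 without knockdown replicate 1. With each array left out in turn, the mean ran from -0.179 (without control replicate 1) to -0.112 (without control replicate 3). Lists matched on mean expression had a smaller shift, with a median of -0.024, and 0 of 10000 had a mean as low (percentile 0, lowest -0.091). Members of the drawn lists were picked independently, without any correlation between them, so the percentile cannot show how unusual the list is. The members did move together between replicate arrays: their estimated correlation was 0.228, against the preset 0.01. It was 0.019 with the replicate number as a block and 0.001 without control replicate 1. Whether moving together accounts for the shift stays open. The gap between the groups was 0.012, while the control scores ranged over 0.149. The same list was called in 3 of the other 9 splits, each of which puts control replicate 1 with 2 knockdown arrays, and ribosomal proteins in 6 of them. Whether VAMP7 knockdown lowers the expression of respiratory chain genes therefore stays open.

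YARS2 was 2.04 higher on the log2 scale, measured by 1 probe set, and did not pass in the fit used for the report (adjusted p = 0.461). With 1 siRNA treatment described in the labels, an effect of the siRNA on transcripts other than VAMP7 was not separated from an effect of lower VAMP7, and neither was tested.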
